A study of Mus musculus with 25 samples.

How the data were processed

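RNA was measured in mouse 2-cell embryos and blastocysts, and RNA and DNA methylation in subcutaneous fat. Per the labels' protocols, cDNA made from lysates was amplified over 18 to 20 cycles, fragmented and sequenced as paired ends. The authors deposited FPKM per gene and library with lower and upper confidence bounds, per the file headers, whose layout is that of Cufflinks gene tracking files. The submitters' processing notes name HISAT2 2.1.0, Cufflinks 2.2.1, Cuffdiff, Trim Galore 0.6.4, Bowtie2 2.3.5, deepTools 3.5.0, DiffBind 2.12.0 and Bismark, without roles, and the genome build mm9. Locus starts in the files count from 0 and are given from 1. Each table held 24708 gene loci of 24257 symbols, 244 symbols at more than 1 locus. No mm9 annotation was used here, so exons and untranslated regions are not stated.

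The fat and RRBS tables turned out to be gene ontology enrichment tables, in which the authors deposited a Fisher p-value and an FDR per term, per the file headers, with the numbers of annotated, selected and expected genes. The design had allowed for tables of values, comparisons or regions, so the tests planned for them were replaced by a description of the terms. How genes were selected, in which direction they changed and the gene universe are not given in the sources used here. Terms beyond the leading ones were picked after the tables were seen. Some genes named in these tables are not reported here. The overlap of their symbols was set against the share of genes selected that the table's own expected numbers imply, with an exact binomial test.

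Groups were taken from the sample titles. The labels do not say that replicates came from separate cultures or animals, so p-values of single genes measure only the spread between these samples, which may be technical. The highest Pearson r between 2 libraries of a stage was 0.990, and no tables were identical. Depth was estimated from the deposited bounds, taken as 2 standard deviations of a Poisson count, so it covers counting error only. Of low values (under 40 implied fragments), 36.9% to 44.8% per library came out whole within 0.05, so no count test was run.

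Values were tested as log2(FPKM + 1) with limma 3.58.1 (R 4.3.3, lmFit and eBayes with an intensity trend) on loci with a mean of at least 1 FPKM. The 6 libraries of 2-cell embryos shared a fit, and the 5 blastocyst libraries had their own. Fold changes are on this scale, which understates the change of genes with low values. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists (35 fixed, tested where 5 or more members were measured, 1 locus per symbol) were tested with limma's camera, two-sided, at a preset correlation of 0.01 and again with an estimated correlation. The preset form takes its degrees of freedom from the number of genes, so its p-values do not measure the spread between libraries. The estimated form is limited by the residual degrees of freedom, 3 in either fit. The shared WT libraries were handled by simulating unchanged groups against them, 100 times.

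Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes Fzr1, then, among genes that passed, had no overlap between groups and reached a mean of 5 FPKM in the higher group, the 8 largest rises and 8 largest falls, then up to 3 passing members per direction of each list that passed or held a passing gene. Where no member passed, the 2 of smallest p were named, and where fewer than 10 genes passed, the 10 of smallest p. Names of small RNAs, predicted genes and clone-based genes were counted but not named.

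Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, upper-quartile scaling, no intensity trend, robust estimation, a replicate block, a 2-fold threshold, fits of only the libraries compared and leaving out each replicate. Removal of each library's trend with transcript length (from lengths implied by the bounds), library weights, the list tests other than those with quantile normalization or an estimated correlation, the list median without members listed at 0 in a whole group, and the overlap at unadjusted p were added after seeing the data. The steps were tested on simulated data. For IVF against WT (8246 genes) they recovered 12% of 2-fold and 46% of 4-fold changes with 3 false calls, and for blastocysts (9439 genes) 93% and 100% with 9 false calls. The 200 changed genes were drawn only from loci with a mean of at least 5 FPKM, so recovery below that level was not measured. Noise was normal and independent between genes, at each gene's fitted spread, so the false calls cover that noise only. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, numpy 2.4.6, matplotlib 3.10.9 and statmod 1.5.0 were also used.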

Results

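The series profiled mouse embryos and offspring tissue of the BDF1 strain to ask how early embryos respond to in vitro fertilisation (IVF) and to a raised dose of Fzr1, and what follows in adult fat. Expression tables of 11 of the 25 samples were analysed. These were 2-cell embryos at embryonic day 1.5 labelled WT, sIVF and IVF (2 libraries each) and blastocysts at embryonic day 4.0 labelled Fzr1-OE (3 libraries) and Control (2 libraries). The labels do not say what sIVF stands for. Subcutaneous fat of 4-month-old Fzr1-OE and Control mice was described through the authors' deposited tables of gene ontology terms for RNA (3 libraries per group) and for reduced-representation bisulfite sequencing, RRBS (1 library per group). The 6 H3K9me3 and input libraries were not analysed here. The depth implied by the deposited confidence bounds was 4742698 to 6377606 fragments per 2-cell library and 9324167 to 10483442 per blastocyst library. At 1 FPKM, a value scaled for transcript length and library size, 2 standard deviations of counting error came to 28.0% to 32.1% of a value in 2-cell libraries and 27.5% to 28.5% in blastocyst libraries. Between 10085 and 11860 of 24708 gene loci were above 0 in a 2-cell library and between 13658 and 13947 in a blastocyst library.

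Fzr1 encodes Cdh1, a co-activator of the anaphase-promoting complex, and lies on chromosome 10 from 80829624 to 80841115 (mm9). It was not higher in the blastocysts labelled Fzr1-OE, at 12.7, 15.5 and 17.1 FPKM, than in Control, at 16.5 and 16.5 FPKM. The log2 fold change was -0.13 with a standard error (SE) of 0.16 and a limma adjusted p of 0.713. The groups are therefore called libraries labelled Fzr1-OE throughout, and every direction below rests on those labels. These values cover counted Fzr1 RNA at embryonic day 4.0 only, so Fzr1 protein and the dose at earlier stages are not known. In 2-cell embryos Fzr1 stood at 7.69 and 10.1 FPKM in IVF, at 0.117 and 0.233 FPKM in WT and at 0.239 and 2 FPKM in sIVF. The IVF libraries lay above the WT libraries, but the gene did not pass the test (log2 fold change 3.07, SE 0.72, limma adjusted p = 0.151), nor did it for sIVF against WT (0.72, adjusted p = 0.846) or sIVF against IVF (-2.35, adjusted p = 0.255). Over the alternatives these log2 fold changes ran from 2.79 to 5.05, from 0.08 to 1.65 and from -3.40 to -1.71, in that order. The blastocyst value ran from -0.22 to -0.02.

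**Figure D1:**
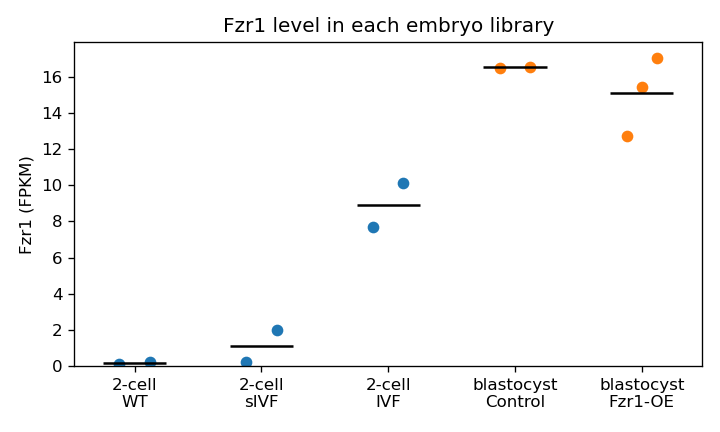
Fzr1 expression (vertical axis, FPKM) in each of the 11 embryo libraries, by group. Each point is 1 library. The 2-cell IVF libraries sit at 7.69 and 10.1 FPKM against 0.117 and 0.233 FPKM in WT, and the blastocyst libraries labelled Fzr1-OE, at 12.7 to 17.1 FPKM, span the Control value of 16.5 FPKM.

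In 2-cell embryos labelled IVF, Hypk, which encodes a partner of the NatA N-terminal acetyltransferase, was 3855 ± 161 FPKM (SD, n = 2) against 1590 ± 39.4 FPKM in WT (SD, n = 2). Hypk, on chromosome 2 from 121282824 to 121284176, rose by a log2 fold change of 1.28 (SE 0.12, limma adjusted p = 0.0259). It was the only gene of 8246 to pass in this comparison, and 0 genes passed in the lower direction, while a filter of 5 FPKM gave 12 genes higher and 9 lower. At an unadjusted p under 0.05 stood 1024 genes (12.4%), of which 566 were higher and 458 lower in IVF, and 678 of 8269 without WT replicate 2. The groups did not overlap for 3476 genes (42.2%), against a chance share of 33.3%. Among the 10 genes of smallest p, 9 did not pass and shared a limma adjusted p of 0.0584. The histone H2A gene H2afj stood at 419 ± 24.3 FPKM in IVF and 142 ± 13.2 FPKM in WT (SD, n = 2 each), and the nucleosome-binding gene Hmgn2 at 1139 ± 26.3 and 606 ± 43.5 FPKM. Mif, a cytokine gene, stood at 514 ± 32.5 and 214 ± 16.9 FPKM. Hist1h2ao, listed at 2 loci of near-identical sequence and so uncertain, had log2 fold changes of 1.50 and 1.50. Values were lower in IVF for Ptma (133 ± 11.1 against 320 ± 0.919 FPKM), for the sterol-regulated Insig1 (log2 fold change -1.85, SE 0.25), for Myef2 (-1.37, SE 0.18) and for Fubp3 (-2.19, SE 0.30). None of the 29 gene lists tested passed. The smallest camera adjusted p was 0.108, for genes of the 2-cell stage (22 measured, median log2 fold change -0.63, 0 passing singly and 0 adjusted over the list alone). Short transcripts, of which Hypk is 1, ran higher in IVF, with a median log2 fold change of 0.19 in the shortest of 10 equal length classes and 0.01 in the longest. The Hypk log2 fold change ran from 1.03 to 1.32 over 17 alternatives, and the call held in 5 of them. None of these was a fit without 1 of the 6 libraries, where the lone library of a group is assumed to vary like the others.

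For sIVF against WT, limma called 0 of 8246 genes, and 585 (7.09%) stood at an unadjusted p under 0.05. The smallest adjusted p was 0.258, for the homeobox gene Hesx1, which was at 30.2 and 33.3 FPKM in WT listed at 0 in both sIVF libraries, and at 8.89 and 2.79 FPKM in IVF. Sdha and Polr2a, genes used by every cell, were also listed at 0 in 1 2-cell library each, but reached at most 6.49 and 1.36 FPKM in any. Other such genes that were checked, among them Gapdh and Tbp, were above 0 in every 2-cell library. These values do not show how often a gene at the WT level of Hesx1 is listed at 0. Among the genes that shared the next adjusted p, 0.466, were Aqp11 at 8.79 ± 2.19 FPKM in sIVF against 47.1 ± 0.479 FPKM in WT (SD, n = 2 each), Galk1 at 1.73 ± 0.194 against 18.7 ± 3.92 FPKM and Usp22 at 234 ± 17.7 against 97.3 ± 10.3 FPKM. For sIVF against IVF limma called 0 genes, with 974 (11.8%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0560. Genes at this value included Hypk (log2 fold change -1.10, SE 0.12), Actb (1.67, SE 0.20), Ptma (1.40, SE 0.17), the ribosomal RNA transcription factor gene Rrn3 (1.43, SE 0.18) and the m6A reader gene Ythdf2 (1.27, SE 0.18), which did not pass. None of 29 lists passed in either comparison, with smallest camera adjusted p of 0.396 for sIVF against WT and 0.573 for sIVF against IVF. The call count for sIVF against IVF rose to 32 with a filter of 5 FPKM and to 15 after quantile normalization.

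In blastocysts, 216 genes rose and 181 fell in the 3 libraries labelled Fzr1-OE against 2 Control libraries, of 9439 tested with limma. A change of at least 2-fold was seen in 116 of them, 80 higher and 36 lower. Among single genes, the ATP-gated channel gene P2rx7 was at 3.82, 7.25 and 7.47 FPKM in libraries labelled Fzr1-OE and at 0 and 0.048 FPKM in Control. The oxytocin gene Oxt rose from 0.938 ± 0.0910 FPKM (SD, n = 2) to 6.32 ± 2.30 FPKM (SD, n = 3, log2 fold change 1.86, SE 0.31, adjusted p = 0.0112). Cbr2, a carbonyl reductase gene, rose by 1.75 on the log2 scale (SE 0.27) and Oas1e by 1.60 (SE 0.31). Tdpoz5, a member of a family of near-identical copies, rose at 2 loci by 3.32 and 2.97, and its reads cannot be told apart from those of its copies. The non-coding Snhg9 was listed at 0 in all 3 libraries labelled Fzr1-OE and at 4.97 and 20.1 FPKM in Control. Myl9, a myosin light chain gene, fell from 54.1 ± 6.43 FPKM (SD, n = 2) to 11.4 ± 3.25 FPKM (SD, n = 3, log2 fold change -2.17, SE 0.20, adjusted p = 6.25e-04). The zinc transporter genes Slc39a2 (-1.44, SE 0.21) and Slc39a1 (-1.34, SE 0.31) and the mitochondrial protein gene Gbas (-1.59, SE 0.28) fell too. Slc39a1 stood at 18.9 and 46.5 FPKM in the Control libraries, and Gbas at 18.9 and 41.9 FPKM. Without Control replicate 2 their log2 fold changes were -0.72 and -1.04, and neither call held. Unadjusted p was under 0.05 for 1860 genes (19.7%), and groups did not overlap for 3532 (37.4%, chance share 20%). The 397 calls came down to 87 without Control replicate 2, 177 without Control replicate 1, 185 without Fzr1-OE replicate 3 and 210 without Fzr1-OE replicate 2, and the lone Control library is then assumed to vary like the other group. They came down to 0 with no filter on low values, and to 41 with no intensity trend, 30 of them higher and 11 lower.

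Of the 33 gene lists tested in blastocysts, 9 passed camera at the preset correlation, 4 higher and 5 lower in libraries labelled Fzr1-OE, and 0 passed with an estimated correlation. That estimate was -0.020 for genes of the 2-cell stage and 0.0002 for p53 targets, below the preset 0.01. Their larger p-values there thus come from the few residual degrees of freedom, not from correlation between genes. Some other lists, such as oxidative phosphorylation (0.153), lay above the preset. Genes listed for the 2-cell stage, the first wave of embryonic transcription, rose in 10 of 14 measured members (10 adjusted over the list alone), with a median log2 fold change of 1.54 and a camera adjusted p of 1.46e-10 (adjusted p = 0.125 with an estimated correlation). In 3 of the 10 both Control libraries were listed at 0, and the median of the other 11 members was 1.18. The list median was 0.56 with no filter on low values and 1.04 with a filter of 5 FPKM, where 4 members rose, and the list passed under both. Tdpoz4, like Tdpoz1 and Tdpoz3 in this list a gene with near copies and so uncertain, was at 6.89, 6.21 and 6.72 FPKM in libraries labelled Fzr1-OE and listed at 0 in both Control libraries. Ddit4l rose from 4.58 ± 0.799 FPKM (SD, n = 2) to 14.4 ± 2.44 FPKM (SD, n = 3, log2 fold change 1.46, SE 0.20). Plk2, a p53-regulated kinase gene that both lists hold, rose from 6.80 ± 1.54 to 22.7 ± 1.75 FPKM (log2 fold change 1.61, SE 0.17). In the 2-cell WT libraries Plk2 stood at 0 and 0.026 FPKM, Ddit4l at 7.40 and 1.30 FPKM and Tdpoz4 at 7.60 and 11.5 FPKM. The name of the list thus does not mean that each member was high at the 2-cell stage here. Of 39 measured p53 targets 7 rose (14 adjusted over the list alone) and 0 fell, with a median of 0.39 and a camera adjusted p of 4.07e-07 (adjusted p = 0.125 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 30.5 ± 4.12 to 67.6 ± 4.92 FPKM (log2 fold change 1.13, SE 0.12, adjusted p = 0.00107), and Ccng1 by 0.91 (SE 0.11). Of 37 proteasome genes 13 rose (24 higher and 1 lower adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 8.01e-05 (adjusted p = 0.312 with an estimated correlation), among them Psmb7 by 0.45 (SE 0.08) and Psmd7 by 0.43 (SE 0.07). Of 23 heat shock genes 4 rose (8 higher and 1 lower adjusted over the list alone), with a median of 0.14 and a camera adjusted p of 0.0343 (adjusted p = 0.396 with an estimated correlation). The small heat shock protein gene Hspb1 rose from 84.8 ± 19.1 to 198 ± 13.5 FPKM (log2 fold change 1.23, SE 0.13), and the chaperone genes Hspa8 and Hsp90aa1 by 0.29 (SE 0.05) and 0.27 (SE 0.05). The heat shock call ended without Fzr1-OE replicate 3 (adjusted p = 0.135) and without Control replicate 1 (0.263), over a range of 0.00296 to 0.263 in 15 alternatives. The numbers of members that passed singly came down without Control replicate 2 to 3 for genes of the 2-cell stage, 3 for p53 targets, 0 for the proteasome and 1 for heat shock. Without Control replicate 1 they were 3 for p53 targets, 1 for the proteasome and 2 higher and 1 lower for heat shock. Without Fzr1-OE replicate 3 they were 4 for p53 targets, 1 higher and 1 lower for the proteasome and 1 for heat shock, and without Fzr1-OE replicate 2 they were 2 for the proteasome and 2 for heat shock. With no intensity trend 5 genes of the 2-cell stage, 1 p53 target and 0 of the others passed, and with no filter 0 in any of the 4 lists.

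Trophectoderm genes, markers of the outer lineage of the blastocyst, fell in 9 of 36 measured members (19 adjusted over the list alone), with a median log2 fold change of -0.42 and a camera adjusted p of 1.50e-08 (adjusted p = 0.169 with an estimated correlation). The keratin gene Krt18 fell from 3864 ± 5.89 FPKM (SD, n = 2) to 2393 ± 75.1 FPKM (SD, n = 3, log2 fold change -0.69, SE 0.04, adjusted p = 1.93e-04). Its partner Krt8 changed by -0.61 (SE 0.05) and the placental gene Plac1 from 138 ± 3.12 to 49.5 ± 4.60 FPKM (log2 fold change -1.46, SE 0.10). A list of mammary and skin epithelium, which shares 8 genes with the trophectoderm list, fell in 4 of 15 members (8 lower and 1 higher adjusted over the list alone), median -0.34, camera adjusted p = 4.28e-04 (adjusted p = 0.222 with an estimated correlation). Among 21 primitive endoderm genes 3 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.18 and a camera adjusted p of 0.0191 (adjusted p = 0.312 with an estimated correlation). Lrpap1 (-0.33, SE 0.06), Sdc4 (-0.93, SE 0.20) and Aldh18a1 (-1.19, SE 0.25) fell, and the endoderm transcription factor gene Gata6 rose (0.72, SE 0.16). Of 31 epiblast genes 2 rose and 2 fell (4 and 3 adjusted over the list alone), and that list did not pass (median 0.09, camera adjusted p = 0.193). Spic rose by 0.88 (SE 0.09) and Dppa2 by 0.52 (SE 0.06), and Upp1 (-0.72, SE 0.10) and Sall4 (-0.68, SE 0.15) fell. Sdc4 stood at 372 and 663 FPKM and Sall4 at 156 and 240.4 FPKM in the Control libraries. Without Control replicate 2 the log2 fold changes were -0.51 for Sdc4 and -0.38 for Sall4, and neither call held. Oxidative phosphorylation genes fell in 17 of 79 members (30 adjusted over the list alone) and rose in 0, with a median of -0.18 and a camera adjusted p of 1.14e-06 (adjusted p = 0.399 with an estimated correlation). The cytochrome c oxidase gene Cox6b1 fell from 1894 ± 22.5 to 1386 ± 46.7 FPKM (log2 fold change -0.45, SE 0.05, adjusted p = 0.00127), and Atp5l and Uqcr11 changed by -0.38 (SE 0.06) and -0.35 (SE 0.06). Extracellular matrix genes had 0 of 7 members passing (1 lower adjusted over the list alone), a median of -0.18 and a camera adjusted p of 0.0343 (adjusted p = 0.344 with an estimated correlation), with log2 fold changes of -0.89 (SE 0.26, adjusted p = 0.0931) for Lamb1 and -0.68 (SE 0.25, adjusted p = 0.179) for Timp1. Lamb1 is 1 of 4 genes that this list shares with the primitive endoderm list. The primitive endoderm call ended without Fzr1-OE replicate 1 (0.0660) and with a filter of 5 FPKM (0.302), over a range of 0.0136 to 0.302 in 15 alternatives. The extracellular matrix call ended without Fzr1-OE replicate 1 (0.139), Control replicate 1 (0.104) or Control replicate 2 (0.0612) and with no filter (0.367), over a range of 0.0138 to 0.367 in 14, and its median was not below 0 with no filter. Oxidative phosphorylation members that passed singly came down to 3 without Control replicate 1, 3 without Control replicate 2 and 5 without Fzr1-OE replicate 3. For mammary and skin epithelium 2 members passed without Control replicate 1 and 2 without Control replicate 2. For primitive endoderm 0 passed without Control replicate 2, Fzr1-OE replicate 2 or Fzr1-OE replicate 3, and 0 rose and 2 fell without Control replicate 1 or Fzr1-OE replicate 1. With no intensity trend 2 trophectoderm members, 1 mammary and skin epithelium member and 0 of the others passed, and with no filter 0 in any of these lists.

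**Figure D2:**
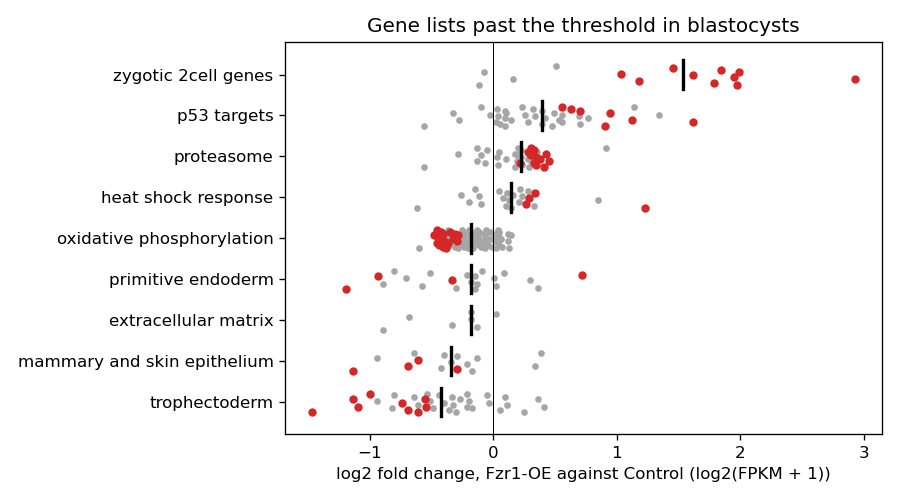
Log2 fold change of the members of gene lists in blastocyst libraries labelled Fzr1-OE against Control (n = 3 and 2), on the log2(FPKM + 1) scale. Each point is a gene, red where it passed the limma test, and black bars mark list medians, which run from 1.54 for genes of the 2-cell stage to -0.42 for trophectoderm genes.

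Changes under IVF at the 2-cell stage were set against those of libraries labelled Fzr1-OE at the blastocyst stage over 6802 genes measured in both. Across genes, which are not independent replicates, Pearson's r was -0.0608 and Spearman's rho -0.0661. An r as large in size came from 9 of 30 pairings of splits of the libraries (permutation p = 0.3, two-sided, smallest possible 0.0333). Hypk, higher in IVF, fell in libraries labelled Fzr1-OE, the only gene called in both (expected 0.0179, Fisher's exact p = 0.0179, adjusted over 4 direction pairs 0.0717). With 1 gene called for IVF, this p is only the share of the 6802 genes that were called lower in blastocysts, 122. The pairs for genes lower in IVF held 0 IVF genes, so their outcome was fixed. The test therefore says nothing beyond that gene. The IVF and sIVF changes share the WT libraries. Their r over 8246 genes was 0.471, against 0.502 simulated with no effect, and their covariance 0.332, against 0.239 simulated and 0.300 from the residual variance. With 2 WT libraries the controls could not be split with 2 in each part, so part of the excess in covariance may come from the shared controls. The r showed no excess. No gene could be called in both comparisons, since sIVF against WT had 0 calls.

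In subcutaneous fat, the authors' deposited table for Fzr1-OE against Control RNA held 1605 gene ontology terms, of which 564 had an FDR under 0.05, naming 449 gene symbols in all. Blood microparticle had the smallest FDR in the authors' deposited table, and general terms on responses to stimuli, wounding and defense stood between the narrower ones named here. These terms of the authors' deposited table were blood microparticle (29 selected genes, 5.49 expected, FDR 1.14e-10), immune response (80 selected genes, FDR 4.3e-09), fibrinolysis (9, 0.49 expected, FDR 3.04e-07) and inflammatory response (42, 14.8 expected, FDR 6.75e-07). The blood microparticle genes in the authors' deposited table included the plasma protein genes Alb, Apoa1, Fga, Fgb, Fgg and Plg. Of the thermogenic fat genes, the authors' deposited table named Ucp1, Cidea, Dio2 and Elovl3. The authors' deposited table also named the macrophage and inflammation genes Adgre1, Itgam, Tnf, Il1b, Clec7a and Tlr2 and, among lymphocyte genes, Cd22, Ptprc, Cxcl13 and Gzma. No direction of change was read for any gene of the authors' deposited table.

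For DNA methylation in the same tissue, the authors' deposited table held 632 terms, 80 of them with an FDR under 0.05, naming 119 symbols. Among the 10 terms of smallest FDR in the authors' deposited table were system development (54 selected genes, 29.3 expected, FDR 0.0013), neuron migration (8, 1.04 expected, FDR 0.0036) and cell migration (22, 7.93 expected, FDR 0.0036). Negative regulation of transforming growth factor beta signalling (5, 0.37 expected, FDR 0.00432) was carried in the authors' deposited table by Bcl9l, Ldlrad4, Pmepa1, Prdm16 and Tgfb1i1. With 1 library per group the methylation difference has no replicate check. The symbols of the authors' deposited table for methylation and of that for RNA overlapped in 3, Esr1, Plekhg6 and Scml4, against 2.94 expected (exact binomial p = 0.770, two-sided).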

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

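Length removal, library weights and the list tests other than quantile normalization and estimated correlation were chosen only after the results were seen. The IVF against WT count of 1 became 0 with a pseudocount of 0.1, no filter, quantile normalization, no intensity trend, only the 4 libraries compared, length trend removed, and in every fit without a replicate (0 to 0). It became 21 with a filter of 5 FPKM, which tests fewer genes. Quantile normalization moved the median of all genes from 0.09 to -0.02. The sIVF against IVF count of 0 became 32 with the filter of 5 FPKM, 15 with quantile normalization and 1 with the length trend removed, and the sIVF against WT count stayed at 0 in every setting run. The blastocyst count of 397 became 116 with a 2-fold threshold, 0 with no filter (2209 at an unadjusted p under 0.05), 41 with no intensity trend, and 87 to 350 without a replicate. With the replicate block, which drops Fzr1-OE replicate 3 and leaves 1 residual degree of freedom, it was 172. Same-numbered libraries did not deviate together (r of -0.003, 0.074 and -0.001 in 2-cell pairs, -0.008 in blastocysts). No pairing by replicate number was thus seen, which does not exclude one. The replicate numbers are those of the sample titles, and the deposited files of some libraries carry others. Under the block 33 of 74 named genes kept their call, the heat shock list lost its own (adjusted p = 0.196, range 0.00296 to 0.263), and 0 proteasome genes passed as higher and 1 as lower. Under a pseudocount of 0.1, the filter of 5 FPKM, quantile normalization, upper-quartile scaling, robust estimation, length removal and library weights the blastocyst count ranged from 395 to 452. With an estimated correlation the adjusted p became 0.125 for genes of the 2-cell stage, 0.125 for p53 targets, 0.399 for oxidative phosphorylation and 0.169 for trophectoderm, and these 4 lists passed in all 15 other alternatives. Of 74 named blastocyst genes that passed, 24 to 62 kept it without a replicate, 10 with no intensity trend and 0 with no filter, and none reversed. At a stricter FDR of 0.01, terms numbered 326 for fat and 25 for RRBS. The cause was not tested unless stated. At 1 FPKM counting error alone gave 2 standard deviations of 27.5% to 32.1% of a value.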

Other observations

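The test on primitive endoderm genes, the length set used for the shortest transcripts, the removal of length trends and the overlap at unadjusted p were chosen only after the result was seen. Metabolic and stress lists that did not pass as lists in blastocysts as reported still held genes that did. In libraries labelled Fzr1-OE, the glycolytic enzyme genes Tpi1 (log2 fold change -0.92, SE 0.11, limma adjusted p = 0.00191) and Aldoa (-0.40, SE 0.06) fell, 2 of 19 measured glycolysis members (3 adjusted over the list alone, camera adjusted p = 0.155). The fatty acid carrier gene Fabp3 fell from 3002 ± 26.2 FPKM (SD, n = 2) to 1835 ± 72.3 FPKM (SD, n = 3, log2 fold change -0.71), 1 of 2 fatty acid oxidation genes that fell among 23 (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0690). That list passed after length trends were removed (camera adjusted p = 0.0401), the adjusted p was 0.429 with an estimated correlation, and no other alternative was run for it. Of the endoplasmic reticulum and integrated stress response, the asparagine synthetase gene Asns (36.3 ± 2.09 against 73.5 ± 6.10 FPKM), the amino acid transporter gene Slc3a2 (log2 fold change -0.39, SE 0.09) and Nupr1 (-2.16, SE 0.38) fell, and the chaperone genes Dnajb9 (0.70, SE 0.13) and Hsp90b1 (0.37, SE 0.09) rose. That list had 2 members higher and 3 lower (8 and 7 adjusted over the list alone), a median of 0.09 and a mean of -0.04, which differ in sign, and did not pass (camera adjusted p = 0.822). Median and mean also differed in sign for DNA methylation machinery (-0.01 and 0.02) and skeletal muscle (-0.08 and 0.02), and for H3K9 methylation machinery both (-0.02 and -0.02) went against the test, and none of these passed. Among antioxidant genes, the ferritin gene Fth1 (0.57, SE 0.07), Glrx (0.37, SE 0.06) and Gpx3 (0.95, SE 0.17) rose and the glutathione transferase genes Gsta1 (-1.55, SE 0.19) and Gstm2 (-0.61, SE 0.14) fell, and of 43 measured members 5 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.589). Of 53 measured genes of mitosis and anaphase-promoting complex substrates, Cks2 (0.52, SE 0.08), Rrm2 (0.43, SE 0.06) and Ccna2 (0.51, SE 0.11) rose and Tk1 (-0.39, SE 0.08) fell, and the list did not pass (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.942).

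Of the 74 genes of the authors' deposited table for fat RNA that were measured in blastocysts, 3 passed there, Bhmt, Cks2 and Kng1, a share of 4.05% against 4.21% of the other genes. Taking IVF genes at unadjusted p, 21 were higher in IVF and lower in libraries labelled Fzr1-OE (8.88 expected, Fisher's exact adjusted p = 5.12e-04) and 27 the reverse (10.4 expected, adjusted p = 1.56e-05). Same-direction overlaps were 12 (12.4 expected) and 11 (7.48 expected). Genes are not independent, so these Fisher's p-values do not measure the spread between libraries. Over all genes measured in both, r was -0.0608, and 9 of 30 pairings of library splits gave one as large in size (permutation p = 0.3). The overlaps themselves were not set against library splits, so an opposed response is not shown at the level of libraries.

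Log2 fold changes of 2-cell IVF embryos against WT were higher in short than in long transcripts, by a slope of -0.0564 (SE 0.00768) per doubling of length, with medians above 0 in all 10 length classes. A difference in the length correction of short transcripts argued the other way, since the implied change accounted for a share of -0.427 of the shift over 692 of the 822 shortest genes. The value over the 540 with a length in every library was -0.441, a check void at 65.7% of the genes. Variation between libraries in the recovery of short transcripts may account for it, because the steepest slope between libraries of the same group reached 1.06 of the size of the group slope, or 0.751 after allowing for single libraries. An effect of IVF itself stays open.

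In blastocysts labelled Fzr1-OE, 9 of 36 trophectoderm genes fell and 10 of 14 genes listed for the 2-cell stage rose (camera adjusted p = 0.169 and adjusted p = 0.125 with an estimated correlation, so neither list call held there). A lower share of trophectoderm cells would raise both other lineages. Epiblast genes had a median of 0.09 (camera p = 0.0817, and 0.201 with an estimated correlation), the way this explanation needs. Primitive endoderm genes outside the trophectoderm list went against it, with a median of -0.179 (camera p = 0.00312, and 0.0489 with an estimated correlation). The camera p-values of these 2 lineage lists are not adjusted over lists. The full primitive endoderm list also had a median of -0.18, with 15 of 21 measured members lower and 6 higher. Its camera adjusted p was 0.312 with an estimated correlation. Without Fzr1-OE replicate 1 its median was -0.15 and its call was lost. The lineages thus point apart, and the explanation stays open. A length trend is argued against by a trophectoderm median of -0.403 after its removal, though the correction was small (median shift 0.0155). Slower development stays a hypothesis. Spearman's rho across genes was -0.12 and -0.203 between the change from 2-cell WT to a Control library and the change from the other Control library to the libraries labelled Fzr1-OE. A delay would put rho below 0, but both changes hold the Control level, with opposite sign. A difference particular to the Control libraries would therefore also put it below 0, and no null was run, so rho cannot decide. The classes of genes that follow share this limit. Genes at least 4-fold lower in blastocysts, which a delay would raise, had medians of 0.02 and 0.05 against 0.03 and 0.03 for genes between. This ran as a delay needs in only 1 of the 2 assignments. Genes at least 4-fold higher, at -0.05 and -0.08, ran that way in both. An effect of Fzr1 dose stays untested. Fzr1 RNA was not higher at embryonic day 4.0, but neither Fzr1 protein nor earlier embryos labelled Fzr1-OE were measured.

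In the same blastocysts 17 of 79 oxidative phosphorylation genes fell (adjusted p = 0.399 with an estimated correlation, where the list call was lost). A length trend is argued against by their median of -0.179, below the 2.5th percentile of -0.0263 over 10000 random lists matched on effective length and expression, of which 0 reached it. Of the 10 splits of the 5 libraries into 3 and 2, 1, the real split, gave as many as 397 genes, and the highest other gave 2, but the splits are too few for a share under 0.05.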
